A study of Homo sapiens with 6 samples.

How the data were processed

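The series holds 6 samples of the lymphoma line SU-DHL-4, 3 labelled CON and 3 labelled KD. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected, and the second cDNA strand was marked with dUTP, which keeps the strand of origin. The submitters' processing notes name fastp, HISAT2, StringTie, edgeR and the genome build GRCh38, without versions, roles or order. The annotation release and the strand setting used for counting are not given in the sources used here. Values of overlapping and antisense genes are therefore uncertain.

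The authors deposited a table of the whole series with FPKM per gene and sample, that is fragments scaled by transcript length and library total, per the file headers. The authors' deposited table also gives a linear fold change, its log2, a p-value and a q-value per gene for KD against CON, per the file headers, and GO and KEGG terms per gene. In the authors' deposited table, 79 p-values are listed as 0 and 9187 q-values lie under 0.05. FPKM are not counts, so no count model was fitted here. Low values did not show steps of whole reads: at most 17 of 2771 low genes with a single transcript shared the commonest ratio between a pair of libraries, so depth is unknown. A FPKM divides by length and by the library total, so a rise of a few abundant genes lowers the values of all others. The 10 most abundant genes held 22.0% and 21.7% of the FPKM sum in CON and 25.1% and 25.4% in KD.

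Samples were compared before they were averaged. The replicate 1 columns equalled the mean of replicates 2 and 3 over a fixed divisor, 1.1 in CON and 1.2 in KD, in every gene except ZHX2 in CON (relative tolerance 1e-09). In the authors' deposited table, the fold change equals that of replicates 2 and 3 alone in 23240 of 23241 genes with a value above 0 in both groups, within a tolerance of 1e-06, with ZHX2 again the exception, and equals that of all 3 columns in 0 genes. The design set before the data were examined was for all 6 libraries. It was changed to replicates 2 and 3, 4 libraries in all, because the replicate 1 columns hold no measurement of their own and would be counted as replicates they are not. The fit of all 6 columns is given as an alternative. How the replicate 1 columns were made is not given in the sources used here.

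Genes at 1 FPKM or more in at least 2 of the 4 libraries were tested, 11916 of 29489. The design had asked for 3 of 6 libraries. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 (R 4.3.3), with group as the only term and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of genes with low values. The residual degrees of freedom were 2 and the prior ones 2.85, so the tests lean on a spread shared across genes. In 10 simulations of 2 against 2 libraries with 200 changed genes among 11916, 86.2% of genes changed 1.5-fold and 98.2% of those changed 2-fold were recovered, and 5.53% of the calls were false. Errors were drawn independently with the spread between replicates 2 and 3, and far fewer genes were changed than were called in the data. The false share therefore covers only that spread, not any between cultures. Between the libraries of a group, the median coefficient of variation of genes at 10 FPKM or more was 2.06% in CON and 2.49% in KD. Values for ZHX2 and SLC3A2 were also compared with an exact permutation test.

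Named genes were chosen by a rule set before the data were examined. It takes ZHX2 and SLC3A2, the 8 largest rises and 8 largest falls with a gene symbol, a mean of at least 1 FPKM in the higher group and groups that do not overlap, up to 4 called members with the smallest adjusted p from each fixed gene list, and SLC7A11, GPX4, ACSL4, TFRC and AIFM2. Of 33 fixed gene lists, 30 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01. Of these, 14 passed, 10 up and 4 down. With a correlation estimated per list 0 of 30 passed, the smallest adjusted p being 0.192, and fry called 24. The estimated version rests on the 2 residual degrees of freedom, so little could pass over 30 lists and its failures decide nothing. Estimates for the ATF4, heat shock and hypoxia lists were -0.019, -0.033 and -0.053, below the preset 0.01, so correlation did not raise their p. Those for the called glycolysis, ribosomal protein and interferon lists were 0.171, 0.135 and 0.051. These lie above the preset, so the camera p of these lists may be too small. By contrast fry asks whether members moved in a shared direction, without setting them against other genes. With 6986 of 11916 genes called, many lists pass such a test. Some lists share members, such as SLC3A2 in the ATF4 and transporter lists, and versions without shared members were added after the data were seen. Terms with 10 to 500 tested genes were tested with Fisher's exact test (scipy 1.17.1) among 8675 tested genes with a GO term and 4455 with a KEGG term. GO terms of 1169 tested genes and KEGG terms of 16 were not used here. In a check of the code, a KEGG term with every member set as called ranked 1, and a single draw of random calls gave 0 terms. The first outcome was all but fixed by that setting, so neither check measures how well the test performs. Positions, lengths and GC content came from GENCODE release 29 on GRCh38, which may differ from the authors' annotation release. Lengths were found for 96.8% of tested genes.

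Alternatives set before the data were examined were median-ratio and quantile scaling, no filter and a mean of at least 5 FPKM, limma without trend or with a robust trend, a pseudocount of 0.1, library weights, a replicate block, each replicate left out, other gene set tests, and other backgrounds, sizes and calls for the terms. Added after the data were seen were all 6 columns, protein-coding genes only, lists without shared members, and leaving out each replicate with the tested genes kept. The last was added after leaving out a replicate with the filter applied again had shifted the share of rises among 2-fold calls, and both versions are reported. Figures were drawn with matplotlib 3.10.9.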

Results

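Gene expression was measured by poly(A) RNA-seq in SU-DHL-4, an established human line of diffuse large B-cell lymphoma. The labels give 6 samples, 3 in a group called CON and 3 in a group called KD, and name no gene for KD. The series is concerned with ZHX2, ferroptosis (iron-dependent death through lipid peroxidation) and SLC3A2, and its stated aim was to find enriched pathways. Values were FPKM for 29489 genes, so the sequencing depth of each library is unknown. The replicate 1 columns held no measurement of their own. KD replicate 1 equalled the mean of KD replicates 2 and 3 divided by 1.2 in 29489 of 29489 genes, and CON replicate 1 equalled the mean of CON replicates 2 and 3 divided by 1.1 in 29488, within a relative tolerance of 1e-09. The comparison of KD with CON therefore used 4 libraries, replicates 2 and 3 of each group (n = 2). Their FPKM summed to 267854 and 267622 in CON and to 272992 and 273768 in KD, and 11400 to 11651 genes reached 1 FPKM. Across genes, log2 values correlated at 0.992 between the CON libraries, at 0.991 between the KD libraries and at 0.937 to 0.939 between groups; genes are not independent replicates. Nothing in the labels says that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

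ZHX2, a zinc finger and homeobox transcription factor (ENSG00000178764, GRCh38 chromosome 8, 122781394 to 122974512), was lower in both KD libraries. It stood at 38.5 and 36.7 FPKM in CON and at 11 and 11 FPKM in KD, with means of 37.6 ± 1.31 and 11 ± 0.0580 FPKM (SD, n = 2), a 3.42-fold lower level. On the log2(FPKM + 1) scale it fell by 1.69 (SE 0.0397, limma adjusted p = 3.58e-05). An exact permutation test, two-sided, gave p = 0.333, the smallest that 2 against 2 libraries allow. The ZHX2 row of the authors' deposited table did not hold together: its fold change was listed as -4.62, its log2 cell held an error text, and its CON replicate 1 value of 36 FPKM departed from the 34.2 FPKM that the rule above gives. That value corresponds to a sum over CON replicates 2 and 3 of 79.2 FPKM, against 75.2 FPKM in the authors' deposited table, a difference of 4. For 43 other genes with a listed p within 10-fold and a mean within 2-fold, log2 ratios were at most 0.945 in size. That of ZHX2 was -1.77, so its p in the authors' deposited table did not match its FPKM values as in those genes. ZHX2 was the only gene in CON to depart from the rule, and its level was not taken as a check of the labels.

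SLC3A2, the heavy chain of the cystine transporter and of the large neutral amino acid transporter (ENSG00000168003, chromosome 11, 62856102 to 62888875), also fell. It stood at 75.2 ± 0.392 FPKM in CON and 27.0 ± 0.551 FPKM in KD (SD, n = 2), a 2.79-fold lower level. Its log2 change was -1.45 (SE 0.0295, limma adjusted p = 2.39e-05), with an exact permutation p of 0.333. Its partner in large neutral amino acid transport, SLC7A5, fell from 291 to 118 FPKM (log2 change -1.29, limma adjusted p = 1.57e-05). Its partner in cystine import, SLC7A11, fell from 4.63 ± 0.116 to 3.28 ± 0.0488 FPKM (SD, n = 2; log2 change -0.40, limma adjusted p = 0.00472).

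Genes of ferroptosis moved in both directions. TFRC, the transferrin receptor that takes up iron, rose from 2.67 ± 0.0585 to 20.2 ± 0.803 FPKM (SD, n = 2; log2 change 2.53). AIFM2, which encodes the ubiquinone reductase FSP1, fell from 1.57 to 0.715 FPKM (log2 change -0.58). GPX4, the peroxidase that reduces lipid hydroperoxides, stood at 51.9 and 57.5 FPKM, and ACSL4, which activates polyunsaturated fatty acids, at 8.76 and 9.97 FPKM in CON and KD. Their log2 changes of 0.14 and 0.17 passed the test (limma adjusted p = 0.0256 and 0.0352), but these calls were lost in 7 and 10 of the 19 alternatives. Of 22 tested ferroptosis suppressors, 9 rose (SQSTM1 by 1.33 and GCLC by 0.89 on the log2 scale) and 7 fell, SLC3A2 and SCD (-0.42) among them. Adjusted over the list alone, 10 rose and 7 fell, and the list as a whole did not pass (camera adjusted p = 0.579). Of 22 ferroptosis promoters, 12 rose, among them SAT1 (1.16), ACSL1 (0.86) and PEBP1 (0.71), and 7 fell, also adjusted over the list alone (camera adjusted p = 0.219). Iron handling (5 rose and 3 fell of 22), NRF2 targets (6 and 4 of 16) and glutathione synthesis and use (5 and 6 of 19) did not pass either, with camera adjusted p of 0.281, 0.369 and 0.913.

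**Figure D1:**
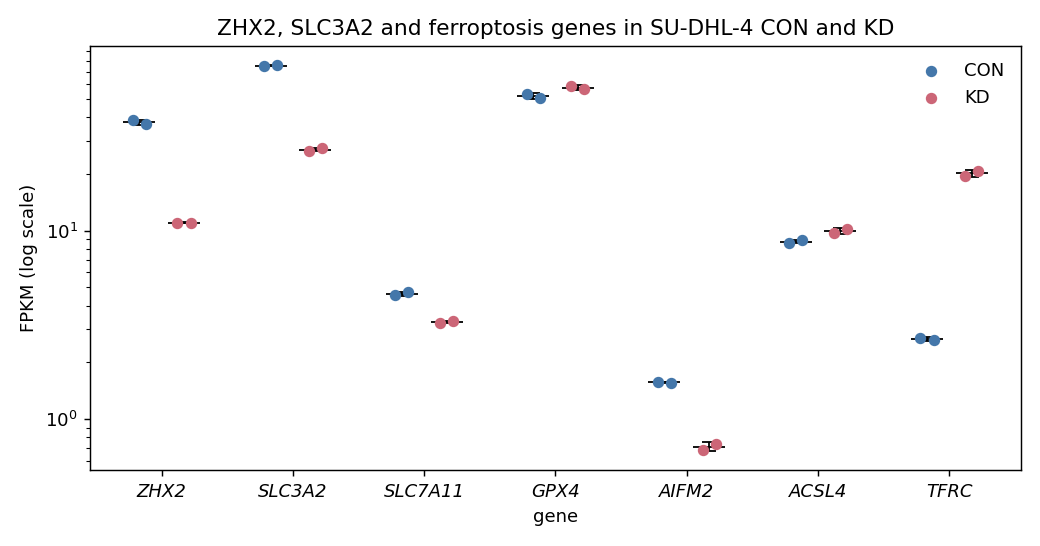
FPKM on a log scale of ZHX2, SLC3A2 and 5 ferroptosis genes in the CON (blue) and KD (red) libraries; each point is a library, and black bars give the group mean ± SD (n = 2). SLC3A2 lies near 75.2 FPKM in CON and 27.0 FPKM in KD, and TFRC near 2.67 and 20.2 FPKM.

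Over all genes, KD and CON differed widely. Of 11916 tested genes, 6986 passed a limma adjusted p of 0.05, of which 3285 rose and 3701 fell, while 7615 had an unadjusted p under 0.05. A change of at least 2-fold was fitted for 615 of them, 347 higher and 268 lower in KD. Which direction held more genes depended on the settings: 3499 rose and 3474 fell under median-ratio scaling, and at 2-fold 563 rose and 609 fell with a pseudocount of 0.1. The largest rises were JUN (log2 change 6.44, from 1.11 ± 0.0710 to 182 ± 2.10 FPKM, SD, n = 2), HSPA1B (5.41), HSPA1A (5.35), EGR1 (4.82), FOSB (4.57), FOS (4.42), DUSP1 (4.39) and the small nucleolar RNA SNORD14E (3.94). HSPA1A and HSPA1B are near-identical copies, so their separate levels are uncertain. The largest falls were MIR1324 (-4.21), RPL36A-HNRNPH2 (-3.91), CLUHP10 (-3.12), CLUHP5 (-2.92), the tryptophanyl-tRNA synthetase WARS1 (-2.85), the immunoglobulin joining segments IGKJ3 (-2.75) and IGHJ1 (-2.69), and MIR142HG (-2.61). Both orders hold on the log2(FPKM + 1) scale. By the ratio of mean FPKM, FOS (628-fold) and FOSB (263-fold) rose more than JUN (163-fold), from CON means of 0.034 and 0.095 FPKM. By that ratio CLUHP5 (111-fold) fell more than MIR1324 (49.5-fold). RPL36A-HNRNPH2 is a readthrough gene and CLUHP10 and CLUHP5 are pseudogenes, so reads shared with related genes leave their levels uncertain. MIR1324 lies within CLUHP10 and SNORD14E within HSPA8, each on the same strand, so neither is independent of its host gene. Among noncoding genes 350 rose and 799 fell of 2171 tested, against 2935 and 2902 of 9745 protein-coding genes. The authors' deposited table lists 1274 genes as up and 1309 as down at 2-fold. Of these, 1160 genes in the authors' deposited table were tested here and 565 passed both thresholds. The authors' deposited table takes its folds from the same replicates without a pseudocount of 1, so a shared direction is no separate evidence, and with a pseudocount of 0.1 the 2-fold count here was 1172.

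**Figure D2:**
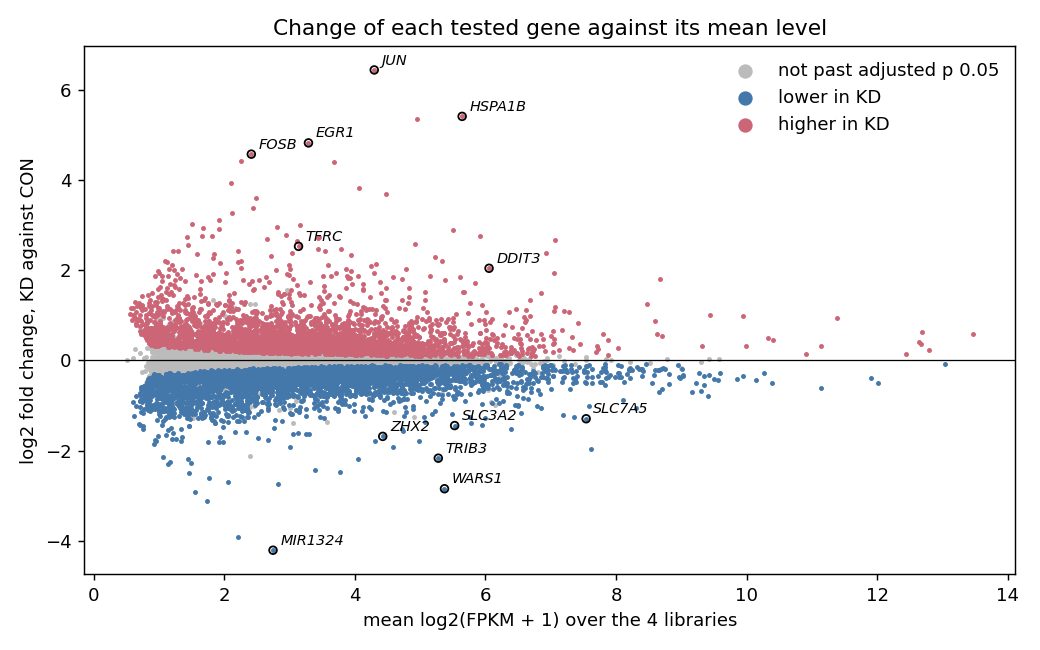
Log2 fold change of KD against CON (vertical axis) against the mean log2(FPKM + 1) over the 4 libraries (horizontal axis) for 11916 tested genes; points are red where higher and blue where lower in KD at a limma adjusted p under 0.05, otherwise grey. JUN lies highest at 6.44 and MIR1324 lowest at -4.21.

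Immediate early and heat shock genes had the highest medians of the 30 tested gene lists. Of 18 immediate early genes, which respond to growth factors and stress within minutes, 17 rose and 1, MYC (-0.59), fell. Their median log2 change was 2.46, and JUNB rose by 2.75 (camera adjusted p = 1.58e-10; adjusted p = 0.192 with an estimated correlation). Of 21 heat shock genes, 20 rose and 0 fell, with a median of 1.16 and large rises of the chaperones HSPA8 (2.38) and HSP90AA1 (1.94) (camera adjusted p = 1.58e-10; adjusted p = 0.192 with an estimated correlation). NF-kB targets rose (14 of 18, with 2 lower), among them GADD45B (3.82), CD83 (2.20), BIRC3 (1.17) and ICAM1 (0.92), at a camera adjusted p of 1.19e-04 and an adjusted p = 0.226 with an estimated correlation. Counts for these 3 lists were the same adjusted over the list alone. Some members, such as FOS and FOSB, passed the filter on low values only through the KD libraries. With no filter on low values, the NF-kB median was 0.27 over 28 members, against 0.56 over 18 (camera adjusted p = 2.46e-06 with no filter). The immediate early median was then 2.05 over 24 members, against 2.46 over 18, and the heat shock median 1.125 over 22, against 1.16 over 21. Here and below, the test with an estimated correlation rests on 2 residual degrees of freedom, so its failure does not decide against a list.

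Genes of hypoxia and glycolysis rose as well. Of 18 hypoxia targets, 16 rose and 0 fell, with a median log2 change of 0.73, including the mitophagy receptors BNIP3 (2.03) and BNIP3L (1.1), P4HA1 (1.85) and PFKFB3 (1.34) (camera adjusted p = 2.24e-07; adjusted p = 0.20 with an estimated correlation). Of 19 glycolysis genes, 15 rose and 2 fell, with ALDOC (1.52), ENO1 (1.5), PGK1 (1.07) and LDHA (0.84) higher in KD (camera adjusted p = 1.21e-04; adjusted p = 0.309 with an estimated correlation). Both counts were the same adjusted over the list alone. With no filter on low values the hypoxia median was 0.64 over 23 members. Cholesterol synthesis genes rose in 17 of 25 and fell in 3 (18 and 3 adjusted over the list alone), with SC5D (1.18), IDI1 (1.03), HMGCS1 (0.92) and INSIG1 (0.82) among them (camera adjusted p = 5.90e-04; adjusted p = 0.226 with an estimated correlation).

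Genes of the ATF4 amino acid response, the program that answers amino acid shortage, fell. Of 30 tested, 28 fell and 1 rose (29 and 1 adjusted over the list alone), with a median log2 change of -0.64 (camera adjusted p = 3.79e-09; adjusted p = 0.192 with an estimated correlation). WARS1 (-2.85), the pseudokinase TRIB3 (-2.17) and SLC7A5 (-1.29) were lower in KD, and SLC3A2, itself a member, had the fourth largest fall of the list. DDIT3, the transcription factor CHOP, was the member that rose, by 2.04. Among 20 amino acid transporters, 12 fell and 4 rose, also adjusted over the list alone, with SLC43A1 (-1.52) and SLC43A2 (-1.07) lower in KD (camera adjusted p = 0.0343; adjusted p = 0.306 with an estimated correlation). Without the members shared with the ATF4 list, 6 of 14 transporters fell and 4 rose (camera adjusted p = 0.511). The transporter call was also lost without KD replicate 2 (camera adjusted p = 0.0753) or KD replicate 3 (0.0692) where the filter was applied again, and without KD replicate 2 (0.0623) where the tested genes were kept.

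Of 27 genes of the unfolded protein response, 16 rose and 5 fell (17 and 6 adjusted over the list alone), with PPP1R15A (2.90), DDIT3 (2.04), HERPUD1 (1.16) and CALR (0.66) higher in KD (camera adjusted p = 0.00693; adjusted p = 0.243 with an estimated correlation). Of 22 p53 targets, 10 rose and 1 fell, including PLK3 (1.32) and GADD45A (0.88) (camera adjusted p = 0.00693; adjusted p = 0.243 with an estimated correlation). Of 12 interferon-stimulated genes, 7 rose and 0 fell, including IRF7 (1.45) and BST2 (0.99) (camera adjusted p = 0.00987, or 0.306 with an estimated correlation). The filter kept 12 of the 30 interferon members with values. With no filter on low values their median log2 change was 0.024, against 0.29, and the list still passed (camera adjusted p = 0.0178). The p53 median was then 0.095 over 28 members, against 0.17 over 22 (camera adjusted p = 4.71e-04 with no filter). These p53 and interferon counts were the same adjusted over the list alone, and both calls were lost among genes with a mean of at least 5 FPKM (camera adjusted p = 0.0612 and 0.104). Of 34 G2/M genes, 21 rose and 3 fell (21 and 4 adjusted over the list alone), including CCNB2 (0.93) and NUSAP1 (0.90) (camera adjusted p = 0.00118; adjusted p = 0.243 with an estimated correlation).

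Ribosomal protein genes and nuclear genes of oxidative phosphorylation fell by small amounts. Of 36 ribosomal protein genes, 35 fell and 0 rose, with a median log2 change of -0.23 (-0.12 under quantile scaling), for example RPS14 (-0.47) and RPL8 (-0.43) (camera adjusted p = 1.88e-06; adjusted p = 0.306 with an estimated correlation). Of 33 nuclear genes of oxidative phosphorylation, 25 fell and 3 rose, with a median of -0.32, for example ATP5MC1 (-1.04), CYC1 (-0.67) and ATP5F1B (-0.50) (camera adjusted p = 1.19e-04; adjusted p = 0.226 with an estimated correlation). Counts for both were the same adjusted over the list alone. The 13 mitochondrially encoded genes went both ways, with 9 higher, such as MT-ATP8 (0.62), and 3 lower, such as MT-CYB (-0.50), also adjusted over the list alone (camera adjusted p = 0.0712). The list passed upward with no filter on low values (0.0118), and the direction of its test turned under quantile scaling. All 37 genes with a mitochondrial (MT-) name, these 13 among them, made up 25.9% and 25.6% of the FPKM sum in CON and 29.9% and 30.3% in KD.

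The 4 fixed lists of B cell genes did not pass as lists. Of 30 germinal centre genes, 10 rose and 11 fell (10 and 12 adjusted over the list alone), with MEF2B (-1.01) lower and CXCR4 (0.79) higher in KD (camera adjusted p = 0.816). Of 27 genes of B cell receptor signalling, 7 rose and 11 fell, with the receptor chains CD79A (-0.88) and CD79B (-0.70) lower (camera adjusted p = 0.724). Of 17 MHC class II genes, 5 rose, HLA-DMA (1.22) among them, and 9 fell (camera adjusted p = 0.579). Of 15 plasma cell and activated B cell genes, 5 rose and 3 fell (camera adjusted p = 0.640). Among 14 members of the BCL2 family, which sets the threshold of apoptosis, BMF fell by 1.22 and BCL2L11 and MCL1 rose by 0.86 and 0.61, and in all 6 rose and 3 fell (camera adjusted p = 0.467). The lists of G1/S genes (14 rose and 10 fell of 33), fatty acid metabolism (15 and 7 of 25), histones (4 and 2 of 11) and MYC and ribosome biogenesis (12 and 11 of 35) did not pass either. The fatty acid list (camera adjusted p = 0.0693) passed in 3 of 19 alternatives, with no filter (0.0171) and without KD replicate 3 (0.0289 with the filter applied again and 0.0494 with the tested genes kept). The MYC list had a median of -0.03, whereas its mean of 0.02 and its test pointed up. Of 5 tested T and NK cell markers, LCK (53.5 to 39.2 FPKM) and NKG7 (1.45 to 0.812 FPKM) fell and PRF1 (1.93 to 2.91 FPKM) rose, the NKG7 call being lost in 9 of 16 and the PRF1 call in 3 of 18 alternatives. Of 3 epithelial and fibroblast markers, TAGLN (1.71 to 2.94 FPKM) and LUM (1.35 to 2.38 FPKM) rose and DCN (3.44 to 1.88 FPKM) fell, and 0 myeloid markers passed the filter. The LUM call was lost in 6 and the TAGLN call in 1 of 18 alternatives. In the ZHX list, HOMEZ (-0.67) and ZHX1 (-0.17) fell beside ZHX2, and the ZHX1 call was lost in 12 of the 19 alternatives.

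**Figure D3:**
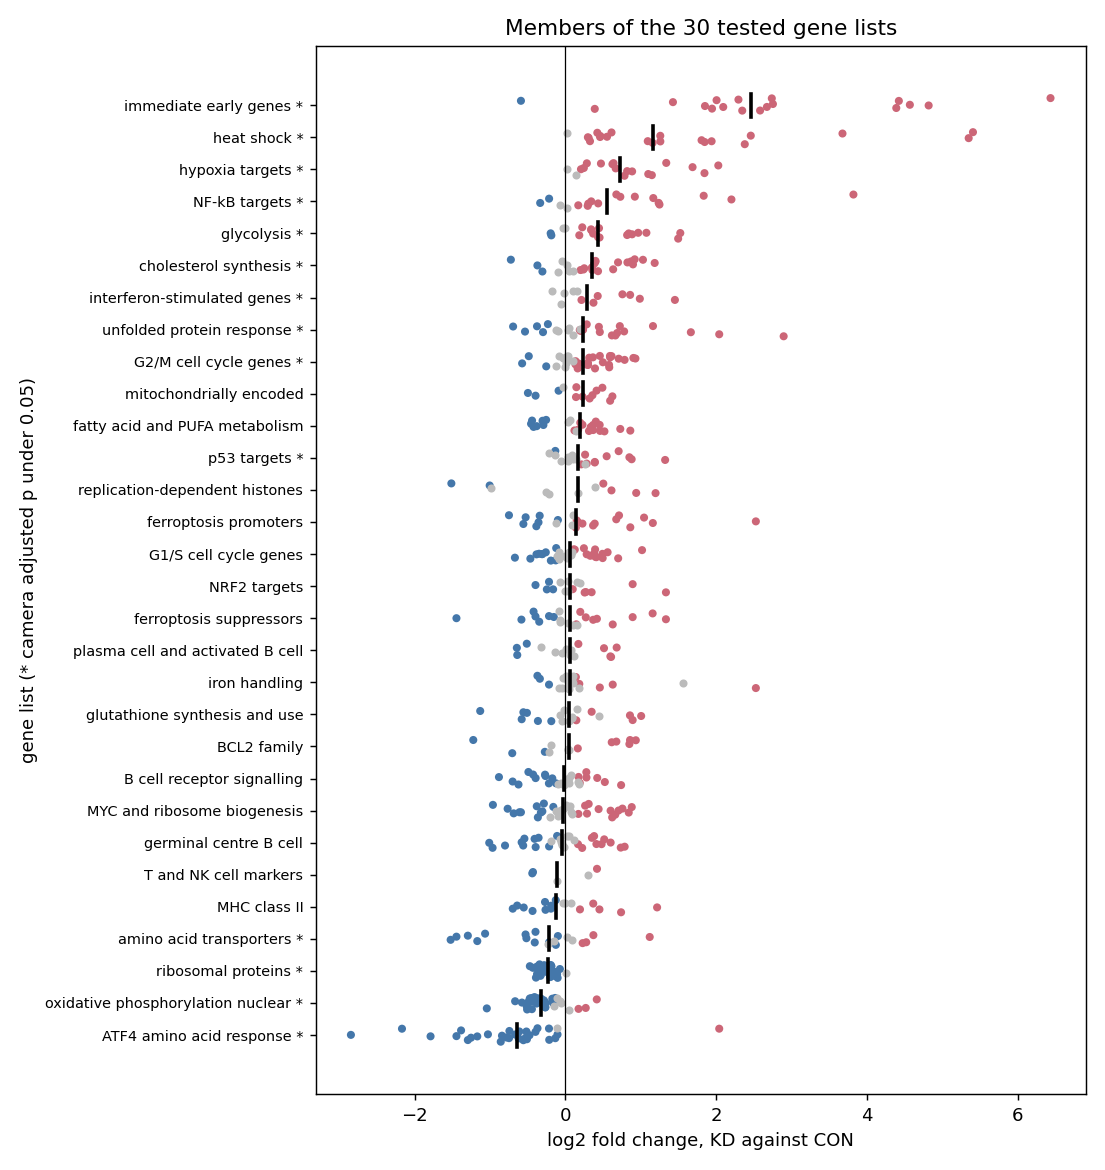
Log2 fold change of KD against CON (horizontal axis) for the tested members of 30 gene lists (vertical axis); points are red or blue where a gene rose or fell at a limma adjusted p under 0.05, otherwise grey, and black lines are list medians. Medians run from -0.64 for the ATF4 amino acid response to 2.46 for immediate early genes.

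Enriched terms of the genes that fell included many of the ribosome and mitochondria. Fisher's exact test treats genes as independent, although all calls come from the same 4 libraries. Its p-values therefore measure only how calls cluster in this comparison. The background was not matched for level, and abundant genes passed with smaller changes, so terms of abundant genes can pass more easily. For example, the SE of the log2 change was 0.0164 for RPL7A (771 FPKM in CON) and 0.0951 for AIFM2 (1.57 FPKM in CON). Cytoplasmic translation held 72 falling genes of 83 tested (adjusted p = 3.47e-24, Fisher's exact test, one-sided), and the mitochondrial inner membrane 200 of 397 (2.15e-15), against 30.3% of all tested genes with a GO term. KEGG terms of falling genes included Ribosome (104 of 134), Oxidative phosphorylation (68 of 120), the citrate cycle (17 of 26) and Proteasome (23 of 44), with adjusted p of 3.76e-27, 2.68e-07, 0.00674 and 0.0410. Genes that rose were enriched in the GO terms centrosome (165 of 402), microtubule (89 of 200) and cell cycle (165 of 417), with adjusted p of 1.55e-04, 0.00108 and 0.00108, against 29% of all. They were also enriched in KEGG MAPK signaling (70 of 150) and p53 signaling (30 of 56), with adjusted p of 0.00879 and 0.0394. In all, 11 GO and 4 KEGG terms passed for genes that rose and 25 and 18 for genes that fell. This split of 15 against 43 depended on the settings: it was 33 against 37 with terms of 20 to 300 genes and 102 against 40 with a background of all tested genes. With only genes past a 2-fold change as calls, 15 KEGG and 0 GO terms passed for rises, and 1 GO term, immunoglobulin complex, and 0 KEGG terms for falls. Of the terms named before this setting, only KEGG MAPK signaling passed there as well. Immunoglobulin complex had also passed for falls in the main setting (15 of 22, adjusted p = 0.0221, Fisher's exact test).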

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

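The alternatives with all 6 columns, with protein-coding genes only, with lists without shared members, and with tested genes kept when a replicate is left out were chosen after the data were seen. Over 19 alternatives 4785 to 7011 genes passed, against 6986 (3285 rises, 3701 falls), with 3499 and 3474 under median-ratio scaling and 2515 and 2471 without CON replicate 3 with the filter applied again, and ZHX2 and SLC3A2 stayed lower in KD. The 2-fold count was 273 (184 rises, 89 falls) among genes with a mean of at least 5 FPKM, 324 (215 and 109) among protein-coding genes and 1172 (563 and 609) with a pseudocount of 0.1, against 615 (347 and 268); the first 2 test fewer genes, and the smaller pseudocount enlarges folds of low genes. Leaving out each replicate in turn gave 4939 to 5054 and 5694 to 5952 genes without a CON and a KD replicate, 510 to 641 at 2-fold, 13 to 15 lists, and log2 changes of -1.72 to -1.65 for ZHX2 and -1.47 to -1.43 for SLC3A2. The lone library of a group is then assumed to vary like the others. Every alternative fit uses the same deposited ZHX2 values, whose row did not hold together, so these fits cannot test that row. With the filter applied again, rises made up 66.4% and 68.6% of 2-fold calls without a CON replicate and 45.7% and 45.3% without a KD replicate, against 56.4%. With the tested genes kept the share was 55.5% to 58.4%, so the shift came from the filter. Leaving out replicate 1 of either group equals the reported fit and gave no value of its own. Of the gene lists, fry called 24 and an estimated correlation, which rests on 2 residual degrees of freedom, 0, against 14. Against 58 enriched terms (15 for rises, 43 for falls), 16 passed with 2-fold calls (15 and 1), 142 against a background of all tested genes (102 and 40) and 70 with terms of 20 to 300 genes (33 and 37); the cause was not tested. No called named gene or called list reversed its direction under any alternative. Of lists that were not called, the test turned direction for mitochondrially encoded genes under quantile scaling, plasma cell genes at a mean of at least 5 FPKM, T and NK cell markers without KD replicate 3 and histones without either KD replicate where the filter was applied again but not where the tested genes were kept, and glutathione genes in 6 alternatives. Of 2343 values of single genes 52 lost their call, and of 566 values of lists 5 lost and 4 gained it. The fit of all 6 columns counts the computed replicate 1 columns as libraries, so its p-values carry no weight. It is nonetheless among the 19 alternatives and in the tallies of values above. It gave 6319 genes (2557 rises, 3762 falls), 5593 of them shared in direction, and a ZHX2 adjusted p of 1.66e-50 (limma). The replicate block gave 6582 genes, 6375 of them shared, 623 at 2-fold, 14 lists, and limma adjusted p of 3.05e-04 for ZHX2 (log2 change -1.69) and 2.12e-04 for SLC3A2 (-1.45). Replicates with the same number did not deviate together (r = 0.0047 across genes), so the numbers are not taken as pairs. Depth is unknown and limits genes near 1 FPKM most.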

Other observations

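The gene groups in the first 2 paragraphs and the tests of the replicate 1 columns, of a single KD library, of the mitochondrially encoded share and of other splits were chosen after the results were seen. Of 12 such groups, 5 passed with camera and 0 with an estimated correlation, which rests on 2 residual degrees of freedom. Of 78 mitochondrial ribosomal protein genes, 47 fell and 6 rose, with a median log2 change of -0.31, for example MRPS18A at -0.91 (camera adjusted p = 1.22e-05 over the 12 groups; adjusted p = 0.201 with an estimated correlation). Of 21 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 15 fell and 2 rose, with SARS1 at -1.38 and MARS1 at -1.19 (camera adjusted p = 0.00248; adjusted p = 0.201 with an estimated correlation), and several of them belong to the ATF4 list. Their mitochondrial counterparts did not pass, with 4 falls and 1 rise of 17 (camera adjusted p = 0.212). Of 38 proteasome subunits, 22 fell and 6 rose, with PSMC4 at -0.88 (camera adjusted p = 0.00806; adjusted p = 0.201 with an estimated correlation).

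Of 43 immunoglobulin segments, 30 fell and 6 rose, with a median log2 change of -0.70, including IGKC at -0.61 and IGHG1 at -0.82 (camera adjusted p = 2.55e-04; adjusted p = 0.201 with an estimated correlation). Short segments share sequence, so single segments are uncertain. Of 11 serine/arginine-rich splicing factors, 9 rose and 2 fell, with SRSF6 at 0.91 and SRSF8 at -0.83 (camera adjusted p = 0.00619; adjusted p = 0.201 with an estimated correlation). Of 34 DNAJ co-chaperones, 13 rose and 12 fell (camera adjusted p = 0.390), although DNAJB1 rose by 3.68 and DNAJB4 by 2.46. Small nucleolar RNAs (camera adjusted p = 0.0782), their host genes (0.212), DUSP phosphatases (0.123), KLF factors (0.0790) and TCP1 chaperonin subunits (0.0782) did not pass either.

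The replicate 1 columns equalled the scaled mean of replicates 2 and 3 in 99.997% of genes or more in each group. Separate libraries would scatter around that mean, as replicates 2 and 3 do around each other, with an SD of log2 ratios of 0.201 in CON and 0.225 in KD. The replicate 1 columns were thus computed from the other columns, with ZHX2 in CON the exception. Why this was done is open. The p for ZHX2 in the authors' deposited table was 2.37e-25, and the log2 ratio computed here from replicates 2 and 3 was -1.77, whereas 43 other genes with a p within 10-fold and a mean within 2-fold had log2 ratios of at most 0.945 in size (median 0.443).

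Immediate early and heat shock genes rose and ATF4 targets fell together. Scaling between libraries does not account for it, since the lowest median of the immediate early and heat shock lists under median-ratio or quantile scaling was 1.16, and the ATF4 list stayed at -0.62 and -0.61. Stress of a single KD library does not either, since the smaller of the KD libraries' median rises over both lists was 1.90. Stress of both KD cultures that does not come from what defines KD, such as handling before lysis, cannot be told apart from an effect of KD itself: 37 of 39 members were higher in both KD libraries than in both CON libraries, and culture and group are the same split. An effect of lower ZHX2 on these genes stays open as an untested hypothesis.

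Ribosomal protein and nuclear oxidative phosphorylation genes fell together. After a trend over transcript length, GC content and mean level was removed, the medians were -0.19 and -0.27 (SE 0.0257 and 0.0789), against -0.23 and -0.32 before, so this trend is not the whole cause. With a fixed FPKM sum, the larger share of the 10 most abundant genes in KD would lower all others by 0.0646 (log2 scale). That of the 37 genes with a mitochondrial (MT-) name would change the rest by -0.0874. Both are smaller in size than either median. The sums were not fixed, at 267854 and 267622 in CON and 272992 and 273768 in KD. Over all tested genes the median log2 change was -0.02, and median-ratio scaling left the list medians at -0.20 and -0.29. Trend and share were each compared alone, not together. Quantile scaling brought the ribosomal protein median to -0.12, so part of that fall may depend on how the most abundant genes are scaled. The group difference itself remains among the open explanations.

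Of the 3 ways to split the 4 libraries into 2 and 2, 1 gave as many genes as the real split, the real split itself. It gave 6986 genes and the highest of the other splits 0. With 3 splits no share under 0.05 can be had.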
